A study of Rattus norvegicus with 10 samples.

How the data were processed

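The series holds RNA sequencing of L4–L6 dorsal root ganglia, the clusters of sensory nerve cell bodies beside the lower lumbar spinal cord, in 10 rat libraries, with the strain given as SD. Per the labels' protocols, animals were divided at random into 2 groups. The painful diabetic peripheral neuropathy (PDPN) group had 1 injection of streptozotocin, a drug that destroys the insulin-producing cells of the pancreas, at 45 mg/kg, and the control group had citrate buffer. Rats with a blood glucose of at least 16.7 mmol/L entered the study, and tissue was taken after 8 weeks. The labels give the glucose check as 72 h after injection in 1 place and as 1 week in another. Total RNA was depleted of ribosomal RNA before library construction, per the labels' protocols. There are 6 control and 4 PDPN libraries. The labels do not say whether each library came from 1 animal, and they give no collection time, batch or cage, so p-values measure the spread between these libraries.

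The deposited gene table holds raw counts for 22192 gene symbols. Per the submitters' processing notes, HISAT2 and HTSeq were used with the rat build mRatBN7.2. Versions, the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes could share reads, and so could near-identical genes such as the alpha- and beta-globin copies, Scd and Scd2, or the RT1 family. The deposited lncRNA table holds estimated counts, which need not be whole, for 20051 long noncoding RNA transcripts. The tool that made these estimated counts is not given in the sources used here, and their unit was read from the values. They were rounded to whole numbers before testing, and 19.1% of the values above 0 rounded to 0. After rounding, 13216 transcripts had at least 1 count in some library. Both tables carried 1 column for each library, and no column was left unmapped.

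Gene names in the gene table were used as deposited. The reference table at hand was built on another assembly, GRCr8, and served for names only; 82.9% of the gene symbols matched it. Of 16239 RefSeq transcript IDs in the lncRNA table, 8807 matched without regard to the version number and 415 with it, and none of 3812 Ensembl IDs matched (0). Of the transcripts tested, 2788 were RefSeq IDs, 1289 of them with a name, and 1035 were Ensembl IDs. Only 3 symbols of matched transcripts were also in the gene table. No coordinates are given, since none came with the tables.

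Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, libraries were scaled by TMM factors, and the quasi-likelihood test with robust estimation (glmQLFit, glmQLFTest) compared PDPN with control, two-sided, with an intercept and the group as the only terms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic. CPM values are TMM-scaled, given as mean ± SD over the libraries of a group. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, over the 45 of 46 lists with 3 or more tested members. The same lists were also tested with an estimated correlation, with fry, and, added later, with an exact permutation of the list mean over all 210 ways to choose 4 of the 10 libraries. Levels of 18 cell type lists, as the mean log2 CPM over the list, were compared by the same exact two-sided permutation test, with Benjamini-Hochberg adjustment over the 18.

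The groups, tests, covariates, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, for each table and direction, the 10 genes of largest absolute log2 fold change among those with adjusted p under 0.05, a mean of at least 1 CPM in 1 group and no overlap between the groups; where fewer than 5 pass, the genes of smallest p fill up to 5 and are named as not passing (for lncRNAs, 5 in each direction). It also names up to 4 members of each list that passed over all genes, or 2 of highest mean CPM where none did, and a fixed set of pain, injury and glucose genes. Of IDs without a name, at most 2 were printed for each direction. Values of a few genes that the rule names are not reported here. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with library quality weights, no low-count filter, a filter of 1 CPM in 4 libraries, no robust estimation, an absolute log2 fold change of at least 1, each library left out in turn, the 8 libraries with shared replicate numbers with and without a block, 1 surrogate variable from sva 3.50.0, the pan-neuronal level as a covariate, and, for lncRNAs, library sizes from the gene table. The red blood cell, fibroblast and satellite glia levels as covariates were added after the data were seen. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

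Gene counts per library came to between 57494560 and 63304029 over 18316 to 18427 detected genes, and the biological coefficient of variation was 13.1%. The lncRNA table held 1688332 to 2156240 estimated counts per library over 7706 to 7958 detected transcripts, with a biological coefficient of variation of 55.6%. Pairs of libraries within a group varied 6.76 to 13.5 times as much as sampling noise over genes with a mean count of at least 20, so none was another library of its group sequenced again. Separate libraries from the same RNA or animal are not excluded by this. The test was tried on simulated data with the real means and library sizes and 200 changed genes. For the gene comparison (16293 genes) it recovered 22% of genes changed 1.25-fold, 62% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, with 7 false calls among 140. For the lncRNA comparison (3823 transcripts) it recovered 0% at 1.25-fold and 1.5-fold, 24% at 2-fold and 44% at 4-fold, with 1 false call among 35. These shares hold for 200 true changes. With fewer, the adjusted threshold is stricter, so they may be too high for the real data.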

Results

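Gene expression was measured by sequencing of ribosome-depleted total RNA from L4–L6 dorsal root ganglia of rats 8 weeks after a single streptozotocin injection (PDPN, n = 4) or a buffer injection (control, n = 6). Libraries held between 57494560 and 63304029 gene counts. The most abundant gene, the mitochondrial COX1, took 1.20% to 1.46% of the counts. Long noncoding RNAs were deposited as a separate table with 1688332 to 2156240 estimated counts per library, of which 1 transcript, XR_005490352.1, took 35.1% to 40.6%. The first principal component of the gene table held 17.9% of the variance and separated the groups on average (exact permutation p = 0.0238, two-sided, n = 4 and 6), with PDPN replicate 3 among the controls. All 10 libraries carried counts from Y-linked genes; Eif2s3y stood at 46.8 ± 2.70 CPM in control and 46.9 ± 1.40 in PDPN, and Kdm5d at 46.7 ± 2.22 and 43.6 ± 3.43.

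The first comparison asked which genes differ between diabetic and control ganglia. Txnip, an arrestin-domain protein that restrains glucose uptake, rose 1.76-fold, from 208.9 ± 17.8 CPM (SD, n = 6) to 367.9 ± 77.2 CPM (n = 4), and its relative Arrdc4 rose from 29.9 ± 3.07 to 40.1 ± 2.52 CPM. Igf1, the insulin-like growth factor 1, fell from 49.4 ± 4.72 to 22.1 ± 5.21 CPM. The largest rise among the named genes was in Alox15, a lipoxygenase acting on polyunsaturated fatty acids, from 0.319 ± 0.120 to 2.79 ± 1.37 CPM, on 10 to 30 counts per control library and 64 to 249 per PDPN library.

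Of 16293 genes tested, 32 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 10 higher and 22 lower in PDPN. In all 32, every PDPN library lay beyond every control library. Such a separation was found in 528 genes, or 3.24% of those tested, against 0.952% by chance. At an unadjusted p under 0.05 there were 2265 genes (1054 higher, 1211 lower), where chance gives about 815. Most called changes were small: the median absolute log2 fold change was 0.41, 28 of 32 were under 1 and 22 were under 0.5.

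Among the genes that rose, Alox15 had a log2 fold change of 3.12 (SE 0.37, edgeR adjusted p = 0.0104) and Txnip of 0.82 (SE 0.11, edgeR adjusted p = 0.0243). Reg3b, a secreted protein of the regenerating gene family, rose by 2.36 (SE 0.36) from a low level of 0.348 ± 0.152 to 1.79 ± 0.888 CPM. The glycine transporter Slc6a9 increased from 3.83 ± 0.432 to 6.35 ± 1.12 CPM, the neutral amino acid transporter Slc38a2 from 294.9 ± 10.5 to 399.9 ± 50.8 CPM, and the ascorbate transporter Slc23a2 from 72.2 ± 2.87 to 84.7 ± 2.77 CPM. The other risers were Ptgfr, the prostaglandin F receptor (log2 fold change 0.40), Oga, the enzyme that removes O-linked N-acetylglucosamine from proteins (0.28), Letm2 (0.30) and Arrdc4 (0.42).

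Among the genes that fell, Igf1 had a log2 fold change of −1.16 (SE 0.13, edgeR adjusted p = 0.0104). The IGF-binding proteins Igfbp3 and Igfbp5 fell by 0.65 (SE 0.10) and 0.66 (SE 0.10) on the log2 scale, to 13.4 ± 1.80 and 59.3 ± 9.44 CPM. Acot1, a cytosolic acyl-CoA thioesterase, fell from 6.33 ± 0.734 to 3.24 ± 0.363 CPM (log2 fold change −0.97, SE 0.12, edgeR adjusted p = 0.0104). The desaturases Scd and Fads2 fell from 285.1 ± 9.07 to 215.0 ± 17.7 CPM and from 201.5 ± 12.1 to 147.7 ± 11.9 CPM, and Dbi, an acyl-CoA binding protein, from 126.1 ± 4.68 to 95.2 ± 10.7 CPM. The chaperone Hsph1 (log2 fold change −0.44), the neuronal pentraxin Nptx1 (−0.41) and the matrix protein Vit (−0.62) also fell. A further 12 called genes lay outside the naming rule. Of these Csn1s1, a casein, is named here after its values were seen: it had the largest fitted fall, from 0.869 ± 0.363 to 0.0825 ± 0.0608 CPM, on 35 to 90 counts per control library and 0 to 9 per PDPN library.

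**Figure D1:**
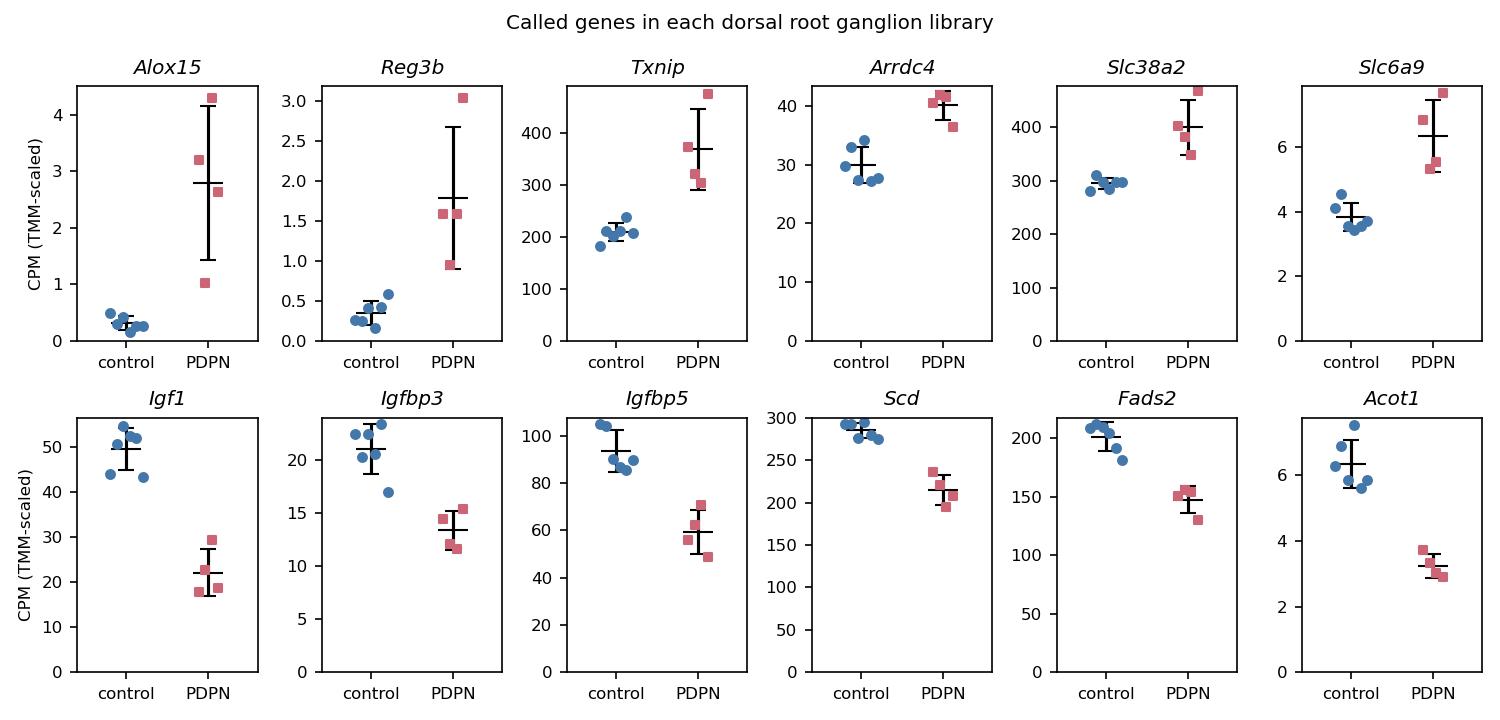
TMM-scaled CPM (vertical axes, from 0) of 12 called genes in each control (n = 6, circles) and PDPN (n = 4, squares) library, with bars for mean ± SD. In each panel every PDPN library lies beyond every control library, as for Txnip (303.2 to 474.9 CPM against 182.9 to 237.9) and Igf1 (17.9 to 29.3 against 43.2 to 54.6).

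The number of called genes rested on single libraries. It was 7, 8, 10, 9, 11 and 49 without control replicates 1 to 6 in turn, and 9, 25, 321 and 11 without PDPN replicates 1 to 4 in turn (edgeR adjusted p under 0.05), while all 32 genes kept their direction in each of these fits. Alox15, Igf1, Acot1, Scd, Fads2 and Dtx4, a ubiquitin ligase of Notch signalling, passed in all 10 fits, with edgeR adjusted p values up to 0.0497. Txnip ranged from an adjusted p of 0.00611 to 0.0775 and Reg3b from 0.0137 to 0.0927 in edgeR. Without PDPN replicate 3 all 32 genes were still called. The count also differed between tools and with cell type levels as covariates. DESeq2 called 509 genes, among them 31 of the 32. With the satellite glia level as a covariate edgeR called 1 gene (Alox15; 831 at an unadjusted p under 0.05), and with the fibroblast level 0 (848 at an unadjusted p under 0.05). Both fits were added later, and all 32 genes kept their direction in them. The satellite glia level ran from 6.891 to 7.118 in PDPN and from 7.120 to 7.269 in control, with no overlap. A fit with it can hardly tell the level from the group, so a lost call or turned direction there does not show that satellite glia account for a change. Against the fit without a covariate, the median ratio of the log2 fold changes of the 32 genes was 0.819 (0.415 to 1.31) with the satellite glia level and 0.883 (0.664 to 1.11) with the fibroblast level. It was below 1 in 23 and 26 of the 32 genes. The SEs of all 32 were larger in both fits (median ratio 1.77 and 1.42), so the calls ended with larger SEs and, in most genes, smaller fold changes. Scd, whose fold change grew, went from −0.41 (SE 0.05) to −0.48 (SE 0.09) and −0.45 (SE 0.07), and Igf1, whose fold change shrank, from −1.16 (SE 0.13) to −0.84 (SE 0.20) and −1.01 (SE 0.17).

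**Figure D2:**
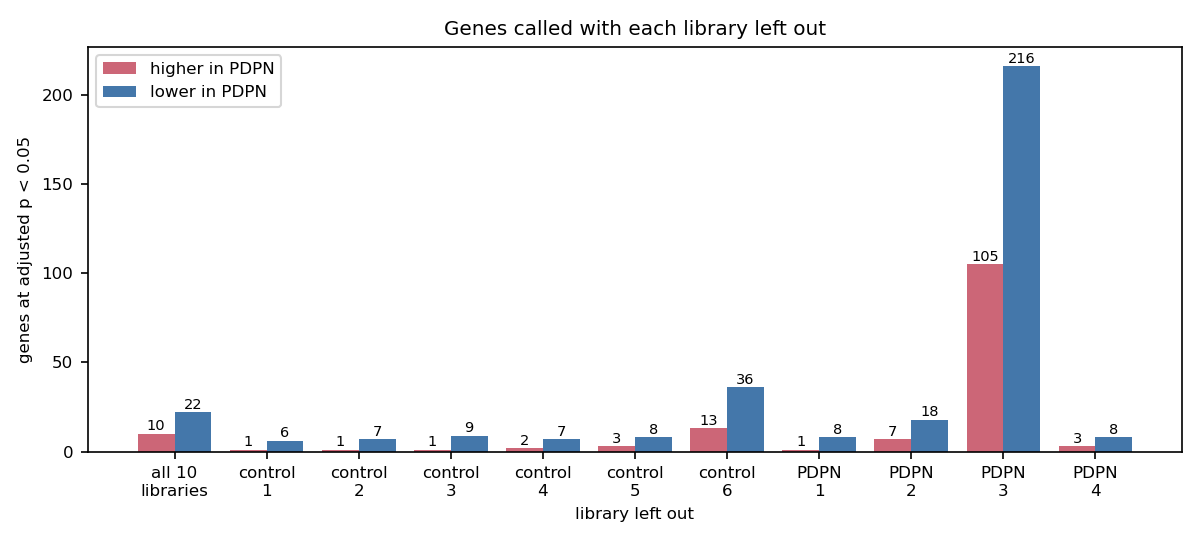
Number of genes at an edgeR adjusted p under 0.05 (vertical axis), higher and lower in PDPN, with all 10 libraries and with each library left out (horizontal axis). Bars for the fit without PDPN replicate 3 reach 105 higher and 216 lower, against 10 and 22 with all libraries.

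Of the fixed set of pain, injury and glucose genes named in advance, only Txnip passed the test. Reg3b and Arrdc4, members of the injury and glucose-sensing lists, also passed but are not in that set. Calca, which encodes the neuropeptide CGRP, stood at 448.2 ± 78.7 CPM in control and 354.1 ± 88.1 in PDPN (edgeR adjusted p = 0.413), and Tac1 at 51.4 ± 4.49 and 45.9 ± 8.11. The sodium channels Scn9a, Scn10a and Scn11a had log2 fold changes of 0.11, −0.10 and 0.07, and the purinergic receptor P2rx3 0.07. For Trpv1, Trpa1 and Cacna2d1, which encodes the gabapentin-binding calcium channel subunit, they were −0.08, −0.10 and 0.10. The injury markers Atf3, Gal and Npy had −0.24, −0.05 and −0.12. Gfap, an intermediate filament of glia, was at 28.7 ± 6.03 and 14.6 ± 2.62 CPM with no overlap between the groups (log2 fold change −0.98, SE 0.17, edgeR adjusted p = 0.0547). Aif1, a macrophage gene, had −0.40 (edgeR adjusted p = 0.210), and the fasting-response gene Pdk4 had 0.52 (edgeR adjusted p = 0.237).

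The second comparison asked which gene lists, fixed in advance, shifted together. Medians and means of lists are differences of mean log2 CPM with a prior count of 2, the scale camera works on. The value of a single member is its fitted log2 fold change in edgeR. On the fitted scale the sign was the other way for the medians of skeletal muscle (0.03) and non-peptidergic nociceptor markers (0.01) and for the mean of oligodendrocyte and astrocyte markers (−0.03). List members named for passing only when adjusted over the list alone lie outside the naming rule and were chosen after their values were seen. Fatty acid synthesis was the list with the smallest p. Of its 12 measured members, 2 fell over all genes tested (Scd and Fads2) and 8 fell when adjusted over the list alone; 0 rose by either count. Scd2, another stearoyl-CoA desaturase, stood at 5498 ± 474 CPM in control and 4413 ± 154 in PDPN, and Elovl6, a fatty acid elongase, at 191.6 ± 12.8 and 153.9 ± 21.6. The list was called lower by camera (median log2 fold change −0.17, adjusted p = 2.59e-06), with adjusted p = 0.455 with an estimated correlation and adjusted p = 0.0260 in fry. Cholesterol synthesis was also called lower by camera (23 genes, median −0.10, adjusted p = 3.64e-05; adjusted p = 0.677 with an estimated correlation), with 0 members past the test over all genes and 7 lower when adjusted over the list alone, among them Cyp51 (log2 fold change −0.32) and Hmgcs1 (−0.24). Satellite glia markers moved with both lists and share Fasn with the first. With the satellite glia level as a covariate, added later, both lists were still called lower by camera (adjusted p = 0.000174 and 0.00443), as with the fibroblast level (adjusted p = 5.39e-05 and 0.00565). The satellite glia level did not overlap between the groups, so a call kept in that fit decides as little as a call lost.

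Satellite glia, the cells that wrap sensory neuron bodies, were represented by 12 markers. None passed over all genes (0), and 6 were lower when adjusted over the list alone, among them the endothelin receptor Ednrb (86.1 ± 7.02 to 63.1 ± 8.18 CPM) and the potassium channel Kcnj10 (179.3 ± 23.1 to 129.5 ± 18.2 CPM). The 2 most abundant markers, Apoe and Fasn, had log2 fold changes of −0.17 and −0.16. Of the 12 markers, 10 lay below 0 and 2 above, Glul (0.29) and Cdh19 (0.12), neither of which passed adjusted over the list alone. The list was called lower by camera (median −0.19, adjusted p = 0.000712; adjusted p = 0.455 with an estimated correlation; fry adjusted p = 0.0260). With the fibroblast level as a covariate the call was lost (median −0.09, camera adjusted p = 0.0653). Myelinating Schwann cell markers were called lower by camera (15 genes, median −0.16, adjusted p = 0.0223; adjusted p = 0.742 with an estimated correlation), with 0 members past the test over all genes and 1 lower when adjusted over the list alone, Dhh. The myelin gene Pmp22 had a log2 fold change of −0.15. This camera call was lost without control replicate 3 (adjusted p = 0.129), control replicate 5 (0.0913), PDPN replicate 1 (0.287) or PDPN replicate 2 (0.124), with 1 surrogate variable (0.0616) and with the fibroblast level as a covariate (0.575). The direction of the test turned with the satellite glia level (median 0.04, camera adjusted p = 0.852). Oligodendrocyte and astrocyte markers were not called by camera (8 genes, adjusted p = 0.430); their median was −0.17, their mean 0.01 and the direction of the test down, 0 passed over all genes and 1, Gfap, was lower when adjusted over the list alone. Aldh1l1, another member, had −0.18.

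Connective tissue and vessel lists were called lower by camera. Of 44 collagen genes, 0 passed over all genes; adjusted over the list alone, 8 were lower, among them Col1a1 (943.1 ± 149.5 to 602.2 ± 148.3 CPM) and Col1a2 (875.8 ± 98.4 to 636.5 ± 157.4 CPM), and 1, Col6a5, was higher (median −0.21, camera adjusted p = 2.86e-05; adjusted p = 0.677 with an estimated correlation). Fibroblast markers (11 genes, 3 of them collagens of the previous list) had 0 past the test over all genes and 6 lower when adjusted over the list alone (median −0.37, camera adjusted p = 0.000544; adjusted p = 0.677 with an estimated correlation). Pericyte and smooth muscle markers (11 genes) had 0 over all genes and, adjusted over the list alone, 5 lower and 1 higher. Myh11, a smooth muscle myosin, had a log2 fold change of −0.53 and Pdgfrb −0.07 (median −0.08, camera adjusted p = 0.0324; adjusted p = 0.677 with an estimated correlation). That call was lost without control replicate 1 (camera adjusted p = 0.0720), 3 (0.109) or 5 (0.0835), or without PDPN replicate 2 (0.285). Endothelial markers (11 genes) had 0 members past the test by either adjustment, over all genes or adjusted over the list alone, with Vwf at −0.16 and Cdh5 at 0.02 (median −0.11, camera adjusted p = 0.0223; adjusted p = 0.677 with an estimated correlation). Their call was lost without control replicate 6 (camera adjusted p = 0.0574), PDPN replicate 1 (0.118) or PDPN replicate 2 (0.183). With 1 surrogate variable the pericyte and endothelial calls were lost (camera adjusted p = 0.0957 each). For collagens, fibroblast, pericyte and endothelial markers the direction of the test turned with the satellite glia level as a covariate (camera adjusted p = 0.961, 0.983, 0.869 and 0.852). With the fibroblast level, which shares genes with collagens and is the mean of the fibroblast markers, all 4 calls were lost (0.0719, 0.542, 0.3465 and 0.489).

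Blood and immune lists moved in different directions. Red blood cell markers were called higher by camera (9 genes, median 0.60, adjusted p = 0.000481; adjusted p = 0.677 with an estimated correlation), with all 9 members above 0 but 0 past the test over all genes or adjusted over the list alone. Hba-a1 stood at 81.4 ± 23.5 CPM in control and 111.4 ± 32.8 in PDPN, and Hba-a2, which is nearly identical to it, at 35.5 ± 9.77 and 54.5 ± 17.9. Interferon-stimulated genes were called lower (22 genes, median −0.40, camera adjusted p = 2.86e-05; adjusted p = 0.677 with an estimated correlation), with 0 past the test over all genes and 5 lower when adjusted over the list alone, among them Rtp4 (log2 fold change −0.60) and Irf7 (−0.52), while the abundant member Ifi27 had −0.03. The direction of the test turned with the satellite glia level as a covariate (median 0.11, camera adjusted p = 0.841). Macrophage markers were called lower (16 genes, median −0.24, camera adjusted p = 0.00525; adjusted p = 0.677 with an estimated correlation), with 0 over all genes and 1, Adgre1, adjusted over the list alone; Laptm5 and Csf1r had −0.45 and −0.12. The macrophage call was lost without PDPN replicate 2 (camera adjusted p = 0.0617) or 3 (0.0772), or with the satellite glia level as a covariate (0.203). Lymphocyte markers (8 genes, median −0.17, or −0.07 on the fitted scale, camera adjusted p = 0.504) had 0 over all genes and 1 lower adjusted over the list alone, Cd4 (−0.39), with Lck at 0.25. Neutrophil and marrow markers (3 genes, median 0.61, or 1.13 on the fitted scale, camera adjusted p = 0.708) had 0 by either adjustment, over all genes or adjusted over the list alone, with Lcn2 at −0.29 and S100a9 at 1.13.

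Cytokines, chemokines and their signalling were not called (24 genes, median −0.18, camera adjusted p = 0.0749), with 0 members past the test over all genes or adjusted over the list alone and Cxcl12 and Nfkbia at −0.40 and 0.28. They would be called lower without control replicate 3 (camera adjusted p = 0.0357), control replicate 4 (0.0315) or PDPN replicate 1 (0.00268). Complement and antigen presentation (21 genes, median −0.06, camera adjusted p = 0.152) had 0 over all genes and 1 lower adjusted over the list alone, C1s, with B2m at 0.01 and Serping1 at −0.03; it would be called without control replicate 3 (camera adjusted p = 0.0300) or PDPN replicate 1 (0.00916).

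In the list of polyol, hexosamine and glucose-sensing genes, Txnip and Arrdc4 rose by both adjustments, so that 2 of 13 passed over all genes and 2 adjusted over the list alone. A log2 fold change below 0 was found in 10 of the 13 (median −0.08, camera adjusted p = 0.676). Fatty acid oxidation and ketogenesis (24 genes, median 0.00, camera adjusted p = 0.915) had 1 member past the test over all genes and 1 adjusted over the list alone, Acot1, which fell; the direction was up in camera and down in fry. Mitochondrial-encoded genes of oxidative phosphorylation were called higher by camera (13 genes, median 0.14, adjusted p = 0.00404; adjusted p = 0.677 with an estimated correlation), with 0 over all genes and 2 higher adjusted over the list alone, ND6 and ATP8, while the abundant COX1 and COX3 had 0.08 and 0.04. This call was lost without PDPN replicate 3 (camera adjusted p = 0.0762). Nuclear-encoded genes of the same pathway (82 genes, median −0.01, camera adjusted p = 0.401) had 0 by either adjustment, over all genes or adjusted over the list alone, with Atp5f1b at 0.04 and Atp5f1a at 0.00, and would be called without PDPN replicate 2 (camera adjusted p = 0.0383) or with the satellite glia level as a covariate (0.00109). Glycolysis (19 genes, median 0.02, camera adjusted p = 0.633) had 0 over all genes and 1 lower adjusted over the list alone, the hexokinase Hk2, with Gapdh at 0.03 and Aldoa at −0.01. Antioxidant and NRF2 targets (20 genes, median 0.00, camera adjusted p = 0.676) had 0 over all genes and 1 higher adjusted over the list alone, Gclc, with Prdx2 and Gpx4 at −0.06 each.

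Of 6 stress, clock and growth lists, 5 were called by camera. Heat shock proteins were called lower (13 genes, median −0.11, camera adjusted p = 0.00664; adjusted p = 0.677 with an estimated correlation), with Hsph1 as the 1 member that fell over all genes and adjusted over the list alone (301.7 ± 24.4 to 221.8 ± 8.90 CPM). Without PDPN replicate 3 the camera adjusted p was 0.0772. Immediate early genes were called lower (14 genes, median −0.31, camera adjusted p = 0.0209; adjusted p = 0.677 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone and Nr4a1 and Dusp1 at −0.34 and −0.07; the call was lost without control replicate 3 (camera adjusted p = 0.0582) or PDPN replicate 1 (0.139). Cell cycle genes were called lower (15 genes, median −0.14, camera adjusted p = 0.0262; adjusted p = 0.677 with an estimated correlation), again with 0 over all genes or adjusted over the list alone and Pcna and Tyms at −0.03 and 0.08; the call was lost without PDPN replicate 1 (camera adjusted p = 0.0603) or 2 (0.240). Circadian clock genes were called higher (15 genes, median 0.29, camera adjusted p = 0.00443; adjusted p = 0.677 with an estimated correlation), with 0 over all genes and 3 higher adjusted over the list alone (Bhlhe41, Cry2 and Hlf); Cry2 stood at 97.5 ± 4.72 and 118.3 ± 16.3 CPM. Glucocorticoid-responsive genes were called higher (14 genes, median 0.24, camera adjusted p = 0.0324; adjusted p = 0.757 with an estimated correlation), with 0 over all genes or adjusted over the list alone and Tsc22d3 and Per1 both at 0.28. That call was lost without control replicate 1 (camera adjusted p = 0.123), 4 (0.0605) or 6 (0.167), or without PDPN replicate 2 (0.459) or 4 (0.225). With 1 surrogate variable the cell cycle and glucocorticoid calls were lost (camera adjusted p = 0.142 and 0.217). With the satellite glia level as a covariate the direction of the test turned for both (0.241 and 0.284), and the immediate early (0.532) and clock (0.391) calls were lost. The fibroblast level ended the calls of cell cycle (0.301), glucocorticoid-responsive (0.157) and immediate early genes (0.301). Endoplasmic reticulum stress and amino acid response genes were not called (18 genes, median −0.10, camera adjusted p = 0.132), with 0 over all genes and, adjusted over the list alone, 3 lower (Pdia4, Hsp90b1 and Calr) and 1 higher (Asns); Calr had a log2 fold change of −0.48 and Hsp90b1 −0.39.

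**Figure D3:**
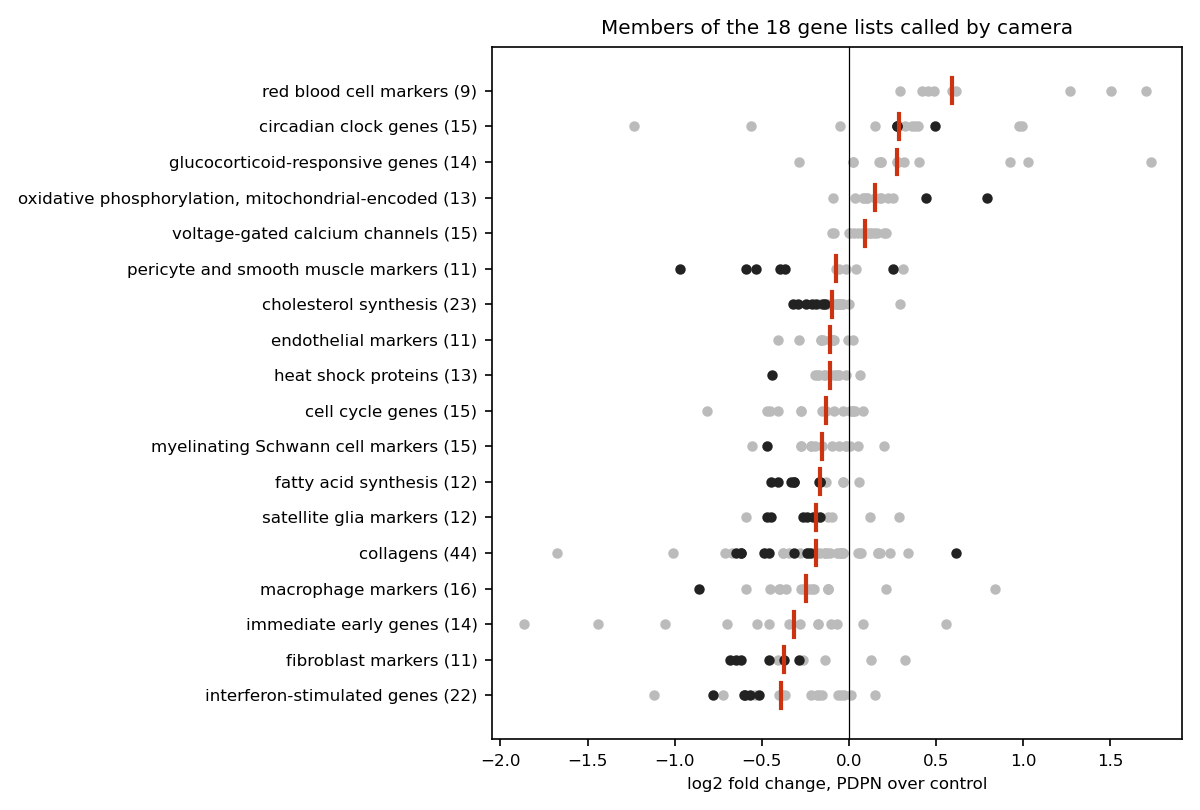
Log2 fold change, PDPN over control (horizontal axis), of each member of the 18 lists called by camera, with the number of members in brackets; dark points passed when adjusted over the list alone and red bars are medians of these fitted values. They run from −0.39 for interferon-stimulated genes to 0.59 for red blood cell markers.

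Of the neuronal lists, none was called by camera. Pan-neuronal markers (15 genes, median 0.07, camera adjusted p = 0.152) had 0 members past the test over all genes or adjusted over the list alone, with Nefl at −0.12 and Tubb3 at −0.06; without PDPN replicate 1 the list would be called higher (camera adjusted p = 0.0309). Peptidergic nociceptor markers (8 genes, median −0.16, camera adjusted p = 0.0691) had 0 by either adjustment, over all genes or adjusted over the list alone, and would be called lower without PDPN replicate 2 (camera adjusted p = 0.00401). Non-peptidergic nociceptor markers (10 genes) had a median of −0.03, a mean of 0.00 and a test direction down, and large myelinated neuron markers (14 genes) a median of −0.03 with Nefm at −0.09 and Nefh at −0.11; in both, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.837 each). C-fibre low-threshold mechanoreceptor markers (7 genes, median 0.06, camera adjusted p = 0.633) had 0 over all genes and, adjusted over the list alone, 1 higher, Zfp521 (0.18), and 1 lower, Cdh9, with Gfra3 at −0.02. Nerve injury and regeneration genes (19 genes) had Reg3b as the 1 member that rose over all genes and adjusted over the list alone; their median was 0.00 and slightly below zero, their mean 0.17 and the direction of the test up (camera adjusted p = 0.690). An exact permutation of that mean, added later, gave p = 0.00476, the smallest that 210 splits allow, and an adjusted p of 0.0714. The mean leans on Reg3b, with a log2 fold change of 2.36, while 9 members lay above 0 and 10 below. The list without Reg3b was not tested.

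Among ion channel and receptor lists, voltage-gated calcium channels were called higher by camera (15 genes, median 0.09, adjusted p = 0.0209; adjusted p = 0.677 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone, Cacnb3 at 0.01 and Cacna1b at 0.05. The call was lost without PDPN replicate 2 (camera adjusted p = 0.3999), with 1 surrogate variable (0.0957) and with the fibroblast level as a covariate (0.168). The direction of the test turned with the satellite glia level (camera adjusted p = 0.577). Voltage-gated sodium channels (13 genes, median 0.03, camera adjusted p = 0.105) had 0 over all genes and 1 higher adjusted over the list alone, Scn4b, and would be called without PDPN replicate 3 (camera adjusted p = 0.0327) or 4 (0.0362). Potassium channels (25 genes, camera adjusted p = 0.915) had a median of −0.01 and a mean of −0.02 with a test direction up; 0 passed over all genes and 1, Kcnd2, was lower adjusted over the list alone, while Kcna1 and Kcna2 had 0.16 and −0.01. Sensory transduction channels (23 genes, median 0.00, camera adjusted p = 0.769) had 0 over all genes and 1 higher adjusted over the list alone, P2rx4, with Piezo2 at 0.04. The opioid and cannabinoid system (12 genes, median −0.03, camera adjusted p = 0.950) had 0 over all genes and, adjusted over the list alone, 2 higher, Oprl1 and Faah, and 1 lower, Oprk1, with Mgll and Dagla at −0.20 and −0.13. GABA and glutamate receptors (28 genes, median 0.04, camera adjusted p = 0.178) had 0 over all genes and, adjusted over the list alone, 3 higher, Grin2d and Gabra5 among them, and 1 lower (Grm8), with Gabbr1 and Gabbr2 at −0.02 and 0.07.

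The lists of other tissues and of library quality were not called by camera, and 0 of their members passed over all genes or adjusted over the list alone. Skeletal muscle markers (9 genes) had a median of −0.20, or 0.03 on the fitted scale, and a mean of −0.25 (camera adjusted p = 0.633), with Acta1 at −0.27 and Mybpc1 at 0.17. Adipocyte markers (4 genes) had 0.04 (camera adjusted p = 0.832), with Lipe at 0.08 and Cfd at −0.15. Bone and cartilage markers (7 genes) had 0.11 (camera adjusted p = 0.421), with Col2a1 at −0.71 and Col10a1 at 0.18, and would be called higher with the satellite glia level as a covariate (camera adjusted p = 0.0353). Sex-specific genes (4 genes) had −0.05 (camera adjusted p = 0.633). Cytosolic ribosomal proteins (81 genes, camera adjusted p = 0.868) had a median of 0.00 just above zero, a mean of −0.02 and a test direction down, with Rpl4 and Rps16 at −0.01 each; they would be called without PDPN replicate 4 (camera adjusted p = 0.000867) or with the satellite glia level as a covariate (4.78e-05). Of the nuclear long noncoding RNAs only Snhg11 was in the gene table (0.28, edgeR adjusted p = 0.232), so that list was not tested.

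In all, camera called 18 of 45 lists, 5 higher and 13 lower, while 0 were called with an estimated correlation and 2 by fry. An exact permutation of each list mean, added later, called 0 lists (smallest adjusted p = 0.0714). With 210 splits it needs at least 5 of the 45 lists at its smallest exact p, or more lists at larger ones. Only 3 were there, so the 0 after adjustment does not by itself show that calls by camera were lost. It gave 10 lists at an exact p under 0.05, 8 of them called by camera, where chance gives 2.25 on average. The others of these 10 were nerve injury and regeneration genes (exact p = 0.00476), whose mean leans on Reg3b, and antioxidant and NRF2 targets (exact p = 0.0333). Lists share genes and are not independent, so a count by chance can lie far from that average. The remaining lists called by camera had exact permutation p values from 0.0619 (immediate early genes) to 0.229 (glucocorticoid-responsive genes). They missed 0.05 before any adjustment, so the limit on the smallest p does not account for them. In drawn splits of the 10 libraries other than the real one, camera called a median of 11 lists and up to 19.

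The third comparison asked whether the share of each cell type differed, with the mean log2 CPM of 18 cell type lists in each library. None passed the exact permutation test after adjustment (0 of 18, smallest adjusted p = 0.0857), and 3 had an unadjusted exact p under 0.05. A list alone at the smallest exact p that 210 splits allow, 0.00476, adjusts to 0.0857 over 18 lists, so no list could pass unless at least 2 were there or more at larger p. Satellite glia markers were lower by 0.22 on the log2 scale (7.18 ± 0.0608 in control and 6.97 ± 0.104 in PDPN, exact p = 0.00476), fibroblast markers by 0.32 (6.22 ± 0.182 and 5.91 ± 0.165, exact p = 0.0429), and red blood cell markers were higher by 0.96 (2.05 ± 0.667 and 3.01 ± 0.487, exact p = 0.0333). Pan-neuronal markers differed by 0.04 (8.61 ± 0.0637 and 8.65 ± 0.0897, exact p = 0.476). Levels are shares of RNA within a library, so they do not count cells.

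**Figure D4:**
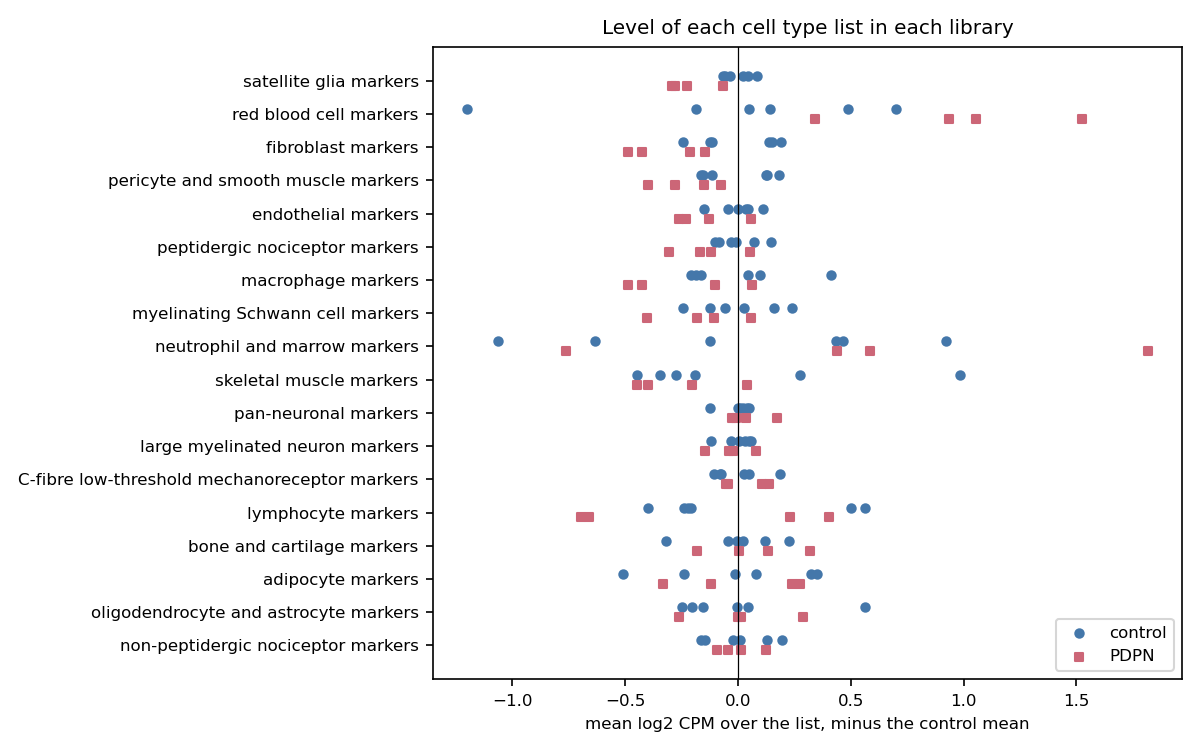
Mean log2 CPM over each of 18 cell type lists, minus the control mean of that list (horizontal axis), in the control (circles, n = 6) and PDPN (squares, n = 4) libraries. Satellite glia markers are lower by 0.22 and red blood cell markers higher by 0.96 on average; 0 of 18 lists passed the adjusted exact permutation test.

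The fourth comparison asked which long noncoding RNAs differ. None passed in edgeR's quasi-likelihood test (0 of 3823 transcripts, smallest adjusted p = 0.370), and 181 had an unadjusted p under 0.05 (84 higher, 97 lower), where chance gives about 191. Of 100 drawn splits of the 10 libraries into 6 and 4, the real one included, 8 gave at least 181, and the median of the others was 138. DESeq2 called 18 (8 higher, 10 lower) and limma-voom 0. The transcripts of smallest p, which did not pass, were LOC102554142 (XR_005495405.1) with 4.50 ± 1.75 CPM in control and 18.97 ± 3.97 in PDPN, LOC102551361 (XR_001842327.2) with 7.61 ± 2.61 and 24.8 ± 6.43, and LOC120102392 (XR_005503900.1) with 28.0 ± 12.5 and 113.8 ± 51.7. Among unnamed transcripts, ENSRNOT00000101467 and XR_005497631.1 had log2 fold changes of 2.18 and 1.81. In the other direction LOC120093578 (XR_005486912.1) had 222.8 ± 47.8 and 135.4 ± 13.1 CPM and LOC102547697 (XR_592335.3) 88.6 ± 15.7 and 49.9 ± 10.6. The unnamed XR_005502823.1 was at 20.2 ± 24.9 CPM in control and at 0 in 3 of 4 PDPN libraries, and XR_005491449.1 was at 7.19 ± 4.13 and 0.404 ± 0.523 CPM. In all of these but XR_005491449.1, every PDPN library lay beyond every control library, as in 46 of the transcripts tested (1.20%, against 0.952% by chance). The gap was narrow for XR_005502823.1 (PDPN up to 1.04 CPM, control from 1.13) and LOC120102392 (PDPN from 43.20, control up to 43.04).

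Known long noncoding RNAs did not pass either. Meg3 stood at 2212 ± 337 CPM in control and 2849 ± 462 in PDPN (log2 fold change 0.37, edgeR adjusted p = 0.987) and Miat at 4580 ± 517 and 5218 ± 638. For Gas5, H19 and Xist the log2 fold changes were 0.08, −0.77 and 0.82. No transcript matched Malat1 or Neat1 by ID. With 24% of simulated 2-fold changes recovered, changes of that size would mostly not be detectable. That simulation held 200 changed transcripts, and with fewer true changes the adjusted threshold is stricter, so 24% may be too high here.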

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

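The counts over other splits of the libraries were planned; the tests on PDPN replicate 3, on satellite glia and on the clock contrast, and the bounds that decide them, were chosen or revised only after the results were seen.

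Of 100 drawn splits of the 10 libraries into 6 and 4, the real one included, 2 gave at least as many called genes as the real 32. That share lies under the bound of 0.05 set in advance, so a count this high is unlikely by chance. This holds only if the libraries are independent, and the labels do not say whether each came from 1 animal. The highest other count was 106, from a split that set PDPN replicates 1, 2 and 4 with control replicate 6 against the rest. Leaving out PDPN replicate 3 alone gave 321. The 106 may therefore reflect the group difference itself or a structure of the samples beside the groups, which was not tested. For lncRNAs the real count was 0, which all 100 splits reach whatever the data (highest other 2), so that count says nothing. At an unadjusted p under 0.05 in edgeR, 8 of 100 splits gave at least the real 181 (highest other 274, median 138). For lists called by camera 5 of 100 splits gave at least the real 18 (highest other 19, median 11), so chance is not excluded for the lists.

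PDPN replicate 3 lay near the controls: over 320 of the 321 genes called without it (1 did not pass the count filter with all 10 libraries), its median position was 0.219 on a scale from the control mean (0) to the PDPN mean (1), against 0.699, 0.908 and 1.22 for PDPN replicates 2, 1 and 4, −0.153 to 0.173 for control replicates 1 to 5 and 0.473 for control replicate 6, each over the genes called without it. Those were far fewer: 25, 9 and 11 genes for PDPN replicates 2, 1 and 4, 7 to 11 for control replicates 1 to 5 and 49 for control replicate 6. The positions are therefore only roughly comparable. The deviation of PDPN replicate 3 from its group mean was still the largest of the 10 after all libraries were thinned to the smallest total, its own (0.361, next 0.323). Unequal library size thus does not account for that deviation, but the position near the controls was not recomputed. In 6 genes, RT1-A2 and RT1-N2 among them, PDPN replicate 3 stood over 4-fold from every other library. Without them its deviation was also the largest (0.356, with them 0.365, next 0.323). Leaving out so few of 16293 genes could hardly change that rank, and strain variants stay open. A mislabelled sample cannot be told apart: with control replicate 6 left out as well, its position over 420 genes was 0.292, between the controls and the other PDPN libraries, with control replicate 6 at 0.411; yet its Alox15 (4.30 CPM), Igf1 (29.3 CPM), Txnip (303.2 CPM) and fatty acid synthesis level (−0.20, controls −0.07 to 0.10) lay with PDPN, and an earlier form of this test, on that list, was replaced. RNA quality stays open too, as its mitochondrial share, the highest at 2.83%, lay outside the range of the other 9 libraries by 0.371 of their SD, under the bound of 1. A milder response of that library to streptozotocin was not tested.

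Satellite glia markers were lower in PDPN by 0.22 on the log2 scale, and the tables argue against neither explanation weighed. A higher share of neuronal RNA would lower all non-neuronal lists alike and stays open: of 13 such lists 8 were lower and 5 higher (red blood cell by 0.96, neutrophil and marrow by 0.52, bone and cartilage, adipocyte, and oligodendrocyte and astrocyte by 0.07, 0.02 and 0.01), and the spread of their differences, 0.365 (median over all splits 0.226), had an exact permutation p of 0.0857. Pan-neuronal markers differed by 0.0429 (SE 0.0518), which decides nothing if neurons supply most of the RNA; earlier forms of this test, on those markers alone and on 5 lists chosen with their differences known, were replaced. A lower share of satellite glia RNA may account for it and cannot be excluded: the spread of the 12 markers' differences was 0.274 (median over all splits 0.152), with an exact permutation p of 0.0905, which decides neither way. Not all markers fell: 10 had fitted log2 fold changes below 0 and 2 above, Glul (0.29) and Cdh19 (0.12). Regulation of these genes within the cells was not tested.

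The clock contrast, the mean of 9 genes led by the Per family minus the mean of Arntl, Clock and Npas2 (3 genes), was higher in PDPN by 1.13 on the log2 scale (control SD 0.971, PDPN SD 0.688). It did not pass the exact permutation test (p = 0.0714), and PDPN replicates 3 (0.76) and 4 (1.69) lay inside the control range of −0.69 to 1.81. A different time of day at collection may account for such a difference and cannot be told apart from chance or from the groups, as no collection time is given; the exact permutation p of the clock list as a whole was 0.1 (adjusted 0.262). Glucocorticoid exposure stays open as well: across the 10 libraries the contrast and 13 glucocorticoid-responsive genes had a Pearson r of 0.534 (permutation p = 0.112) and a Spearman rho of 0.406 (permutation p = 0.248), and after group means were taken out a Pearson r of 0.394 (permutation p = 0.254) and a Spearman rho of 0.261 (permutation p = 0.470); adjusted over these 4 relations the smallest p was 0.339, and without PDPN replicates 2 and 4, the farthest from the median, the first r was 0.229.

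A library far from the rest of its group was found in 17 of 314 groups of values, where chance gives about 16; each is given with the gap to the nearest library as a share of the group's range. Dbi in control had a gap of 0.851 (control replicate 6 at 116.6 CPM, others 126.9 to 128.7), Gapdh in control 0.720 (control replicate 6 at 911.3, others 970 to 992.8), Nr4a1 in control 0.665 (control replicate 6 at 72.7, others 120.7 to 144.9) and Gas7 in control 0.657 (control replicate 6 at 459.5, others 527.9 to 563.6). Fasn in control had 0.627 (control replicate 1 at 1050 CPM, others 825.7 to 909.4), Acta1 in control 0.695 (control replicate 1 at 12.4, others 5.22 to 7.42) and S100a9 0.736 in control (control replicate 1 at 0.726, others 0.0844 to 0.254) and 0.866 in PDPN (PDPN replicate 3 at 1.75, others 0.0818 to 0.305). Nefl in control had 0.698 (control replicate 5 at 3529 CPM, others 4137 to 4400), Dtx4 in control 0.654 (control replicate 4 at 110.9, others 98.0 to 102.5) and Cfd in PDPN 0.925 (PDPN replicate 1 at 1.08, others 1.42 to 1.45).

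Among lncRNAs, LOC102551361 in PDPN had a gap of 0.935 (PDPN replicate 2 at 34.4 CPM, others 21.1 to 22.0) and Gas5 in PDPN 0.879 (PDPN replicate 4 at 243.2, others 183.7 to 190.9). XR_005502823.1 had 0.750 in control (control replicate 5 at 69.0, others 1.13 to 18.1) and 1 in PDPN (PDPN replicate 1 at 1.04, others 0). The pan-neuronal level in control had 0.727 (control replicate 5 at 8.48, others 8.61 to 8.66) and the oligodendrocyte and astrocyte level 0.641 (control replicate 5 at 1.12, others 0.31 to 0.60).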

How the results depend on the processing

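The fits with red blood cell, fibroblast and satellite glia levels and the exact permutation of list means were chosen after the results were seen; the other tests were planned. Of 4281 comparisons of a named value with its value as reported, 3817 kept their direction and side of the threshold or changed sign with no call on either side, 400 lost a call, 55 gained one and 9 changed sign with a call; 248 changed sign in all. Except where a value is given, the cause of each change below was not tested.

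Against 32 called genes (10 higher, 22 lower), upper-quartile factors gave 49 (14 and 35), DESeq2 509 (194 and 315) and limma-voom with quality weights 101 (25 and 76). Counts were 32 with RLE factors, 34 with no filter, 30 with a filter of 1 CPM, 38 without robust estimation and 37 with 1 surrogate variable. A minimum absolute log2 fold change of 1 left 4 (2 and 2), and with an unadjusted p it gave 101 (46 and 55). The pan-neuronal level as a covariate gave 57 (17 and 40), the red blood cell level 101 (21 and 80), the fibroblast level 0 (0 and 0; 848 at an unadjusted p under 0.05) and the satellite glia level 1 (1 and 0; 831 at an unadjusted p under 0.05), in edgeR. With the last 2 levels the SEs of the 32 genes were larger (median ratio 1.42 and 1.77). The satellite glia level did not overlap between the groups, so its fit can hardly tell the level from the group. Leaving out control replicates 1 to 6 gave 7, 8, 10, 9, 11 and 49 and PDPN replicates 1 to 4 gave 9, 25, 321 and 11, a range of 7 to 321 (1 to 105 higher, 6 to 216 lower). All genes called in the report and still tested kept their direction in each of these fits.

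The replicate numbers do not pair the samples: deviations of same-numbered libraries had correlations of 0.00, −0.02, −0.08 and −0.10. On the 8 libraries with shared numbers, edgeR called 54 genes (12 and 42) without a replicate block and 25 (2 and 23) with it, 10 of them among the 32, and camera called 16 lists either way.

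For lncRNAs, where edgeR called 0 (181 at an unadjusted p under 0.05), DESeq2 called 18 (8 and 10), an unadjusted p with a minimum log2 fold change of 1 gave 75 (35 and 40), and limma-voom, the other scalings, filters, designs and left-out libraries gave 0. This table held 1688332 to 2156240 counts per library, with a biological coefficient of variation of 55.6% against 13.1% for genes; which of these limits it was not tested.

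Against 18 lists by camera, an estimated correlation gave 0, fry 2 and the exact permutation of list means 0. That permutation had 10 lists at an unadjusted p under 0.05, 8 of them among the 18. It needs at least 5 lists at its smallest p, or more at larger ones, and 3 were there. The 0 alone therefore does not show lost calls, but the rest of the 18 missed 0.05 before adjustment. The fibroblast level gave 8 (all among the 18). The satellite glia level gave 8 (5 among the 18, with bone and cartilage, nuclear oxidative phosphorylation and ribosomal proteins added). With 1 surrogate variable there were 12, and leaving out 1 library gave 13 (PDPN replicate 2) to 19 (PDPN replicate 4). With the satellite glia level the direction of the camera test turned for 9 lists, with medians of 0.0395 (myelinating Schwann cell), 0.078 (endothelial), −0.13 (pericyte and smooth muscle), −0.0431 (fibroblast), −0.0176 (calcium channels), 0.11 (interferon-stimulated), −0.19 (glucocorticoid-responsive), 0.0069 (collagens) and 0.14 (cell cycle). That level did not overlap between the groups, so these turns do not show what the lists follow.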

Other observations

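The genes in this part were chosen after their values were seen, and no test beyond those of the report was added for them.

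Beside the fall of Igf1, Igfbp3 and Igfbp5, other genes of the insulin and IGF axis did not pass the test. Insr, the insulin receptor, stood at 66.0 ± 2.62 CPM in control (n = 6) and 79.9 ± 8.56 in PDPN (n = 4; log2 fold change 0.27, SE 0.06, edgeR adjusted p = 0.0965), and Igf1r at 112.2 ± 4.02 and 129.8 ± 16.9 (0.21, edgeR adjusted p = 0.205). Igf2, Igfbp2, Igfbp4, Igfbp6 and Igfbp7 had log2 fold changes of −0.34, −0.22, −0.33, 0.10 and −0.09, and the receptor substrates Irs1 and Irs2 −0.08 and 0.05.

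The 12 called genes outside the naming rule were all lower in PDPN by construction, since the rule names every called gene that rose. Gpr37l1, a receptor of glial cells, went from 143.5 ± 12.9 to 110.2 ± 5.77 CPM, Megf10, an engulfment receptor, from 92.8 ± 5.04 to 74.7 ± 4.75, Ttyh1, a membrane protein, from 181.5 ± 4.84 to 150.4 ± 6.21 and Reln, a secreted matrix glycoprotein, from 738.7 ± 39.5 to 573.4 ± 46.9 (edgeR adjusted p = 0.0403, 0.0403, 0.0163 and 0.0243). Satellite glia markers were lower by 0.22 on the log2 scale in the same libraries. Entpd2, an ecto-nucleotidase, lay just outside the threshold, with a log2 fold change of −0.50 (edgeR adjusted p = 0.0511).

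The glucocorticoid-responsive and clock lists had medians of 0.24 and 0.29 on the log2 scale, and 0 members passed over all genes. Of the members with larger differences, Fkbp5 stood at 35.5 ± 10.2 CPM in control and 67.4 ± 31.3 in PDPN, Zbtb16 at 41.6 ± 17.6 and 84.9 ± 46.2, Per2 at 15.1 ± 6.36 and 29.7 ± 10.5, and Arntl at 21.7 ± 6.63 and 14.7 ± 3.75 (edgeR adjusted p = 0.273, 0.338, 0.291 and 0.370).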
